A study of Rattus norvegicus with 6 samples.

How the data were processed

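RNA from 6 samples of rat marrow mesenchymal stem cells, 3 treated with CYSP and 3 with DMSO (CK) for 7 days, was extracted with Trizol and enriched for polyadenylated RNA on oligo(dT) beads before library construction, per the labels' protocols. Per the submitters' processing notes, fastp 0.18.0, HISAT2, StringTie 1.3.1 and RSEM were used, with no role given for any of them. The genome build, the annotation release and the tool that counted reads are not given in the sources used here, so no coordinates are printed. The deposited table of 23091 genes gives raw read counts per gene and sample, per the file headers. If RSEM made these deposited counts, they are estimates that the authors rounded. The same table gives FPKM per sample, per the file headers, and the authors' mean FPKM per group. The authors' log2 fold change is the log2 of the ratio of those means, and the authors' p-value and adjusted p-value come from a test that is not given in the sources used here. Whether counting used strand is not stated, so reads of overlapping and antisense genes may not be told apart.

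Samples were grouped by their titles. Genes were tested on the deposited counts with edgeR 4.0.16 in R 4.3.3 (filterByExpr on the group, TMM scaling, robust dispersion, glmQLFit and glmQLFTest), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The filter kept 12623 genes. A further 6878 genes had no count in any sample and 3590 had counts under the filter. Standard errors were derived from the fold change and the F statistic of the same test. They understate the error of a large fold change when a group has few counts. CPM values are TMM-scaled and given as mean ± SD over 3 samples. Where a group had 0 counts, a fold is a lower bound against 3 counts over the group, and where it had 1 to 3 counts the ratio is given with its 95% Clopper-Pearson counting interval. Totals of 15060933 to 17244700 counts per sample set the precision of low genes.

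Before the data were examined, 40 gene lists were fixed, with 891 different genes, together with the tests, the alternatives and the rule for naming genes. That rule takes in each direction the 8 genes with the largest absolute log2 fold change among those past the threshold with a mean of at least 10 CPM, no overlap between groups and a gene symbol that is not a placeholder. From each list it takes up to 4 members past the threshold with a mean of at least 1 CPM and up to 2 of the minority direction, of which a selection is printed, and it always takes 12 markers. Some genes that the rule takes are not reported here. Of the 891 list genes, 872 were found among the deposited genes, 2 of them by an older symbol, and 675 were tested. The other 19 are not analysed here. For 20 list symbols that stand on several gene identifiers the one with the highest counts was used, so their values are uncertain where reads could be split between copies. Lists were tested with camera (limma 3.58.1) on log2 CPM with a preset correlation of 0.01. KEGG pathways (300) and GO processes (1364) of the deposited annotation with 15 to 300 tested genes were tested in the same way, with adjustment within each source.

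Alternatives were other scalings (DESeq2 size factors, upper quartile, library size only), the DESeq2 1.42.0 Wald test, limma-voom, no filter and a stricter filter of 50 counts in 3 samples, each sample left out, the replicate number as a block, limma with trend on log2(FPKM + 1) of genes with a mean FPKM of at least 0.5, glmTreat against a log2 fold change of 1, a threshold of 2, camera with an estimated correlation, and fry. For DESeq2 the lists and terms were tested with cameraPR on the Wald statistic. The fits with an assumed coefficient of variation and the fit without mitochondrial transcripts were added after the data were seen. The procedure was tested on simulated counts for 12623 genes with the means, dispersions and library sizes of these samples. Only 200 genes were given a change there, whereas 76.1% of the tested genes passed the threshold here. In that setting edgeR recovered 50% of the simulated changes of 1.2-fold, 72.9% of 1.5-fold, 95.8% of 2-fold and 100% of 4-fold, and called 0.0975% of unchanged genes. These rates do not carry over to a comparison in which most genes pass.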

Results

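Messenger RNA was profiled in rat marrow mesenchymal stem cells, the adherent stromal cells of bone marrow, kept for 7 days in neural differentiation medium. The 3 samples named CK received the solvent DMSO and the 3 samples named CYSP received the treatment of that name, which the labels do not spell out. Total counts per sample lay between 15060933 and 17244700, and 3 counts, the limit that a count of 0 allows, corresponded to between 0.174 and 0.199 CPM, the usual scaling of counts to the library total. These limits, and the intervals on single ratios given below, cover counting error only. The question put by the series is how gene expression changes while the treated cells take on a neuron-like state. The labels do not say that the replicates are separate cultures or animals. P-values here set the difference between groups against the spread between these samples, which may be technical. If it is technical, they say nothing about other cultures or animals.

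Relative to the small spread between samples of a group, most of the tested genes differed between treated and control samples. Of 17 tested contractile genes 15 fell, by very different amounts. Tagln, an actin-binding protein of smooth muscle, fell from 3260 ± 101 to 1.3 ± 0.931 CPM (mean ± SD, n = 3 per group). Cxcl13, a chemokine that attracts B cells, rose from 0.765 ± 0.291 to 834 ± 4.87 CPM, and Adipoq, the fat-cell hormone adiponectin, from 0.199 ± 0.253 to 519 ± 13.2 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4828 of the 12623 genes tested were higher in CYSP and 4772 were lower. With an absolute log2 fold change of at least 1 the counts were 1917 higher and 1598 lower. Every CYSP sample lay above or below every CK sample in 77% of the tested genes. For 3 samples against 3, chance gives 10% if the samples are independent and the groups do not differ. The labels do not say that the samples are independent, and all genes share them, so setting 77% against 10% cannot decide about chance. Between samples of a group the Pearson correlation of log2 CPM across genes was 0.991 to 0.992, and between groups 0.813 to 0.816, with genes not being independent replicates. The first principal component held 94.1% of the variance and separated the groups. The common biological coefficient of variation was 0.0393, which is small. With a coefficient of 0.2 assumed in its place, a choice made after the data were seen, 3102 genes were higher and 2801 lower, and with 0.4 the counts were 1496 and 1209. At neither assumed value did most of the 12623 tested genes pass.

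Among the largest increases by the rule fixed for naming genes, Orm1, an acute-phase plasma protein, had no count in CK and 61.4 ± 3.06 CPM in CYSP, at least 1030-fold higher when 3 counts over the group are taken as the floor. Snap25, a component of the synaptic vesicle fusion machinery, had 1 count over the CK group and 2236 over the CYSP group, a ratio of 2450 (95% counting interval 438 to 96600). Ca8 and Ca4, of the carbonic anhydrase family, had 3 and 1 counts in CK, with ratios of 2580 (882 to 12500) and 1450 (259 to 57100). Fam20a, a secretory pathway pseudokinase, had 2 counts in CK and a ratio of 1810 (502 to 15000). Pi15, a secreted peptidase inhibitor, rose by a log2 fold change of 10.78, with 11 counts over the CK group. Among the largest decreases, Actg2, the enteric smooth muscle actin, went from 14349 counts over the CK group to 1 over the CYSP group, a ratio of 13100 (2350 to 518000) in favour of CK. Acta2, smooth muscle alpha-actin, fell from 3960 ± 30.5 to 1.91 ± 1.45 CPM. Acan, the cartilage proteoglycan aggrecan, fell from 631 ± 27.6 to 1.17 ± 0.419 CPM. C1qtnf3 and Pappa2, both secreted proteins, had log2 fold changes of -8.65 and -8.58, with 20 and 8 counts over the CYSP group. Fcrl2 had -9.76, with 4 counts over the CYSP group. Afap1l2, an adaptor protein, kept 2 counts in CYSP, with a ratio of 1080 (299 to 8940) in favour of CK.

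Neuronal markers moved in both directions. Tubb3, the neuronal beta-tubulin, rose from 8.67 ± 1.07 to 37.8 ± 2.59 CPM (log2 fold change 2.12, SE 0.097, edgeR adjusted p = 3.76e-33). Map2, a dendritic microtubule protein, fell from 4.27 ± 0.352 to 1.35 ± 0.19 CPM, and Dcx, a protein of migrating immature neurons, went from 79 counts over the CK group to 3 over the CYSP group, a ratio of 24.1 (7.95 to 119) in favour of CK. Rbfox3, which encodes the nuclear antigen NeuN, had 0 counts in each of the 6 samples, which allows up to 0.199 CPM in the shallowest. Nefl, the light neurofilament, had 3 counts in CK 2 and 0 in the other samples. Nefm, the medium neurofilament, with 5 counts over the CK group and 29 over the CYSP group, and Syp, synaptophysin, with 12 and 23, stayed under the count filter and were not tested. Gfap, an astrocyte filament protein, had 10 counts over the CK group and 1 over the CYSP group and was not tested either. Nes, an intermediate filament of neural progenitors, fell from 38.3 ± 4.08 to 16.8 ± 2.24 CPM. Thy1, expressed by stromal cells and by neurons, rose from 562 ± 6.78 to 661 ± 23.2 CPM.

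**Figure D1:**
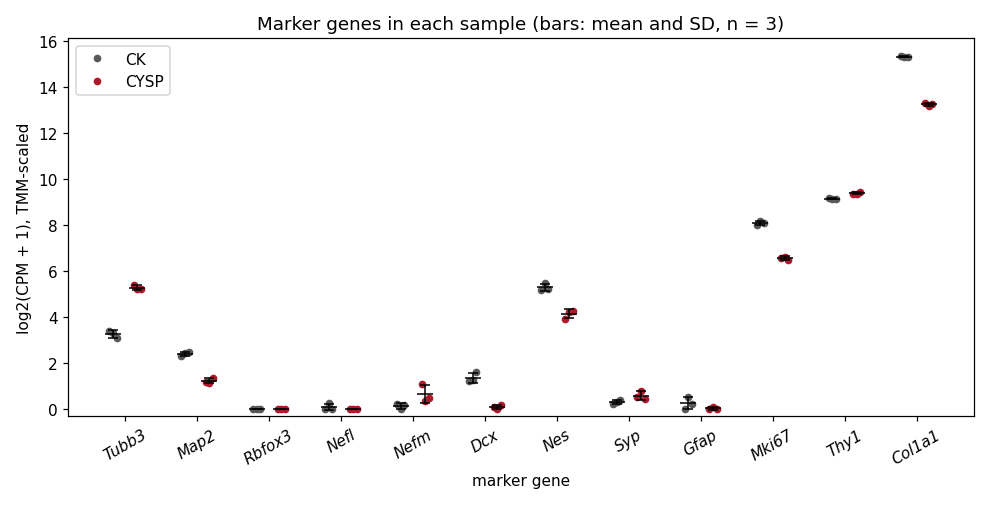
TMM-scaled log2(CPM + 1) of the 12 marker genes fixed before the data were examined, with 1 point per sample and bars for the mean and SD of 3 samples. Tubb3 is higher in CYSP, Map2, Dcx, Nes, Mki67 and Col1a1 are lower, and Rbfox3 lies at 0 in all 6 samples.

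Of the 24 pan-neuronal genes listed, 14 were tested, of which 8 rose, 5 fell and 1 did not pass the test, with the same counts when adjusted over the list alone. Mapt, the axonal protein tau, rose from 0.3 ± 0.211 to 20.4 ± 0.229 CPM, and Nefh, the heavy neurofilament, from 1.94 ± 0.335 to 39.6 ± 2.96 CPM. Gng3, a neuronal G protein subunit, and Ina, a neuronal filament protein, fell, with log2 fold changes of -1.94 and -1.77. The list as a whole did not pass the set test (camera adjusted p = 0.33). The synapse and synaptic vesicle list did (adjusted p = 0.001), with 17 of 21 tested members higher and 2 lower, and adjusted p = 0.27 with an estimated correlation. With DESeq2 this call ended (adjusted p = 0.12). Of the 34 synapse genes listed 13 were not tested, among them Syt1, Syn2, Nrxn3 and Rims1, with at most 18, 6, 3 and 2 counts in a sample. Shank1, 1 of the 2 lower (log2 fold change -0.69), lost its call with DESeq2. It also lost it without CK replicate 2 or 3, without CYSP replicate 1 or 2, and with the replicate number as a block. Sv2b, a synaptic vesicle protein, had no count in CK and was at least 149-fold higher in CYSP, Vamp1, a vesicle fusion protein, rose by a log2 fold change of 4.04 (SE 0.18), and Cplx2, a regulator of vesicle release, fell from 10.5 ± 0.43 to 1.94 ± 0.982 CPM. Of 29 voltage-gated channel genes listed 16 were tested, of which 10 rose and 2 fell (camera adjusted p = 0.042, and adjusted p = 0.45 with an estimated correlation). The calcium channel genes Cacna1h and Cacna1g rose by log2 fold changes of 6.79 and 3.26, and the potassium channel gene Kcnd3 fell by 3.29 on the log2 scale. This channel call ended with DESeq2 (adjusted p = 0.25), limma-voom (0.11), limma-trend on FPKM (0.12) and the stricter filter (0.065), and also without CYSP replicate 1 (adjusted p = 0.054) and without CYSP replicate 2 (adjusted p = 0.051).

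Most genes of the transmitter lists were under the count filter, and none of those lists passed the set test. Of 19 glutamatergic genes 8 were tested, with 4 higher and 3 lower (camera adjusted p = 0.89). The vesicular glutamate transporter Slc17a7 rose from 0.142 ± 0.194 to 3.77 ± 0.666 CPM. Of 19 GABAergic genes 5 were tested, with 1 higher and 3 lower (adjusted p = 0.53). Ache, acetylcholinesterase, was the only tested gene of 14 on the cholinergic and motor neuron list and rose from 0.651 ± 0.241 to 7.94 ± 0.636 CPM (adjusted p of the list 0.36). Of 6 tested monoaminergic genes 4 rose and 2 fell (adjusted p = 0.58), with Gch1, which makes the tetrahydrobiopterin cofactor, at a log2 fold change of 3.07. Slc18a2, 1 of the 2 lower (-0.39), lost its call without CK replicate 1 and without CYSP replicate 1 or 3. Its call was also lost with DESeq2, with limma-voom and with the replicate number as a block. En1, 1 of the 4 higher (0.59), lost its call without CK replicate 2 or CYSP replicate 3. Of 29 proneural transcription factors 6 were tested, with 2 higher and 3 lower (adjusted p = 0.97). Sox4 rose from 40.3 ± 2.06 to 154 ± 4.45 CPM and Sox11 fell from 3.18 ± 1.11 to 0.257 ± 0.223 CPM. Of 11 tested neural progenitor genes 5 rose and 5 fell (adjusted p = 1), and Vim, vimentin, fell from 3610 ± 33.4 to 971 ± 14.4 CPM. In this list the median log2 fold change was 0.14 and the mean -0.14.

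Of 32 tested axon guidance genes 17 rose and 15 fell (camera adjusted p = 0.73), among them the guidance genes Draxin and Sema3a, with log2 fold changes of 8.31 and 5.5, and Sema3e, which fell by 3.95. Of 14 tested neurotrophic genes 9 rose and 4 fell (adjusted p = 0.15). Ptn, the growth factor pleiotrophin, rose from 1.96 ± 0.471 to 266 ± 3.57 CPM, and Ntrk3, a neurotrophin receptor, had no count in CYSP and was at least 75.9-fold lower there. The astrocyte list passed the set test, with 8 of 10 tested genes higher and 2 lower (adjusted p = 0.019, and adjusted p = 0.27 with an estimated correlation). Of its 14 listed genes, Gfap, Aqp4, Gjb6 and Acsbg1 stayed under the count filter, with at most 7, 0, 0 and 3 counts in a sample. The list members Aldh1l1, a folate enzyme, and Ndrg2 rose by log2 fold changes of 5.72 and 3.13, and the transcription factor gene Sox9 fell from 30.1 ± 2.71 to 1.34 ± 0.48 CPM. Of 5 tested oligodendrocyte genes 2 rose and 2 fell (adjusted p = 0.67), and 3 were lower when adjusted over the list alone. Cnp, 1 of the 2 higher (log2 fold change 0.23), lost its call without CK replicate 1 or CYSP replicate 1. It also lost it with library size only and with limma-trend on FPKM. Of 8 tested Schwann and neural crest genes 2 rose and 6 fell (adjusted p = 0.25), among them Snai2, a transcription factor of mesenchymal cells, at a log2 fold change of -3.22.

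Most contractile genes and most TGF-beta and YAP/TAZ targets were lower in CYSP. The lists share members, so their results are not separate. Tagln and Acta2 stand on the contractile and TGF-beta lists, Ccn2 and Tgfb2 on the TGF-beta and YAP/TAZ lists, and Lats2 on the YAP/TAZ and Hippo lists. Of 17 tested contractile genes 15 fell and 1 rose, with a median log2 fold change of -4.52 (camera adjusted p = 9e-07, and adjusted p = 0.13 with an estimated correlation). Of 21 tested TGF-beta targets 18 fell and 2 rose, and 19 fell when adjusted over the list alone (adjusted p = 5.8e-06, and adjusted p = 0.15 with an estimated correlation). Tgfb3, a TGF-beta ligand, fell from 441 ± 29.6 to 17.8 ± 0.241 CPM. Of 22 tested YAP/TAZ targets 18 fell and 2 rose (adjusted p = 2.1e-05, and adjusted p = 0.13 with an estimated correlation). The matricellular genes Ccn1 and Ccn2 fell from 587 ± 11.8 to 24.7 ± 0.195 CPM and from 5240 ± 108 to 302 ± 9.55 CPM. Of 23 tested Hippo pathway components 16 fell and 6 rose (adjusted p = 0.021, and adjusted p = 0.34 with an estimated correlation). Vgll3 and Tead4, a cofactor and a transcription factor of the pathway, had log2 fold changes of -2.83 and -2.98, and the cadherin gene Dchs1 of 2.02.

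Matrix and lineage genes were split. Of 38 tested collagen and matrix genes 16 rose and 21 fell (camera adjusted p = 0.43). Col1a1, the main chain of type I collagen, fell from 40700 ± 960 to 9670 ± 436 CPM, and the collagenase gene Mmp13 rose from 97.3 ± 8.46 to 17900 ± 83.5 CPM. Of 22 marrow stromal genes 13 rose and 8 fell (adjusted p = 0.42), with Itga11, a collagen receptor, at a log2 fold change of -5.02 and the growth factor receptor gene Pdgfra at 1.32. Of 11 tested osteogenic genes 4 rose and 6 fell (adjusted p = 0.73), and Tnfrsf11b, the decoy receptor osteoprotegerin, fell by 6.19. Of 7 tested chondrogenic genes 4 rose and 3 fell (adjusted p = 1), with a median log2 fold change of 1.38 and a mean of -0.09. Of 10 tested adipogenic genes 7 rose and 2 fell (adjusted p = 0.08), among them Dgat2, a triglyceride synthesis enzyme, with a log2 fold change of 3.71, and Fabp4, a fatty acid carrier of fat cells, which fell by 0.94.

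Cell cycle genes were lower in CYSP. Of 35 G2/M and mitosis genes 32 fell, none rose and 3 did not pass the test, with a median log2 fold change of -1.66 (camera adjusted p = 2.3e-09, and adjusted p = 0.34 with an estimated correlation). Cdc20, an activator of the anaphase-promoting complex, fell from 39.6 ± 6.35 to 5.2 ± 0.783 CPM, and the proliferation marker Mki67 fell from 270 ± 14.4 to 92.6 ± 5.37 CPM. Of 30 tested S phase genes 24 fell and 3 rose (adjusted p = 4.2e-04, and adjusted p = 0.34 with an estimated correlation). The S phase call ended with DESeq2 (adjusted p = 0.1). Tk1, thymidine kinase, fell by 2.51 on the log2 scale, and its symbol stands on several gene identifiers, so its reads may be split. Of 26 cell cycle inhibitors and p53 targets 13 rose and 9 fell (adjusted p = 0.48), with the inhibitor gene Cdkn1a rising from 36.2 ± 1.28 to 146 ± 3.45 CPM.

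HIF-1 target genes were higher in CYSP. Of 35 listed genes 34 rose and 1 fell, with a median log2 fold change of 1.44 (camera adjusted p = 3.5e-10, and adjusted p = 0.35 with an estimated correlation). Egln3, a prolyl hydroxylase, rose from 2.65 ± 0.611 to 171 ± 6.41 CPM, Pfkfb3, a regulator of glycolysis, from 21.2 ± 0.601 to 254 ± 6.36 CPM, and Adm, the vasodilator peptide adrenomedullin, from 5.63 ± 0.95 to 114 ± 1.57 CPM. Of 19 tested cAMP/CREB response genes 16 rose and 1 fell (adjusted p = 1.1e-04, and adjusted p = 0.13 with an estimated correlation), with Rgs2, a regulator of G protein signalling, rising from 4.23 ± 1 to 146 ± 6.79 CPM.

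The lists for the other signalling pathways did not pass the set test. Of 27 tested JAK/STAT genes 9 rose and 12 fell (camera adjusted p = 0.92), with a median log2 fold change of -0.12 and a mean of 0.34. Of 30 PI3K/AKT components 14 rose and 10 fell (adjusted p = 0.9), and the adaptor genes Irs1 and Irs2 moved apart, with log2 fold changes of 2.9 and -2.05. In this list the median was -0.02 and the mean 0.08. Of 27 ERK/MAPK response genes 12 rose and 11 fell (adjusted p = 0.73), with the feedback inhibitor gene Spry1 at 5.2 and the immediate early gene Fosb at -4.71. Of 13 tested Wnt targets 8 rose and 3 fell (adjusted p = 0.25), among them Axin2, a feedback inhibitor, with a log2 fold change of 2.31. Of 13 tested BMP targets 6 rose and 4 fell (adjusted p = 0.9), with Id1, an inhibitor of differentiation, at 4.11. In the deposited KEGG annotation, Hippo signaling pathway had an adjusted p of 0.078 with 70 of 124 genes lower, and HIF-1 signaling pathway 0.16 with 50 of 96 higher. JAK-STAT signaling pathway had 0.59, MAPK signaling pathway 0.63 and PI3K-Akt signaling pathway 0.88, while the smaller term Hippo signaling pathway - multiple species had 0.043, with 18 of 25 genes lower and adjusted p = 0.48 with an estimated correlation.

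Inflammatory genes rose while leukocyte markers fell. Of 22 tested cytokine and chemokine genes 17 rose and 5 fell, with a median log2 fold change of 2.75 (camera adjusted p = 9.9e-04, and adjusted p = 0.56 with an estimated correlation). The growth factor gene Csf3 rose from 0.419 ± 0.161 to 387 ± 7.87 CPM and Il6, interleukin 6, from 11.8 ± 2.21 to 951 ± 6.47 CPM. Il1b and Tnf, cytokines made mainly by macrophages, fell, with log2 fold changes of -1.83 and -1.8. Of 21 tested macrophage and leukocyte genes 15 fell and 3 rose (adjusted p = 0.0034, and adjusted p = 0.39 with an estimated correlation). Lyz2, lysozyme, fell from 883 ± 54.2 to 108 ± 4.07 CPM, and Cd163, a scavenger receptor, had 2 counts over the CK group and 761 over the CYSP group, a ratio of 416 (115 to 3440). Of 9 tested endothelial genes 4 rose and 4 fell (adjusted p = 0.93), and of 21 interferon response genes 4 rose and 9 fell (adjusted p = 0.54). Of 23 stress response genes 8 rose and 13 fell (adjusted p = 0.25), with Atf3 and Ddit3, transcription factors of the integrated stress response, at log2 fold changes of -2.75 and -1.42. Of 19 tested cholesterol synthesis genes 5 rose and 8 fell (adjusted p = 0.73). All 13 mitochondrially encoded transcripts rose, with a median log2 fold change of 1.35 (adjusted p = 3.4e-06, and adjusted p = 0.27 with an estimated correlation), and they held 4.96% to 5.06% of the counts in CK samples and 10.9% to 11.1% in CYSP samples.

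**Figure D2:**
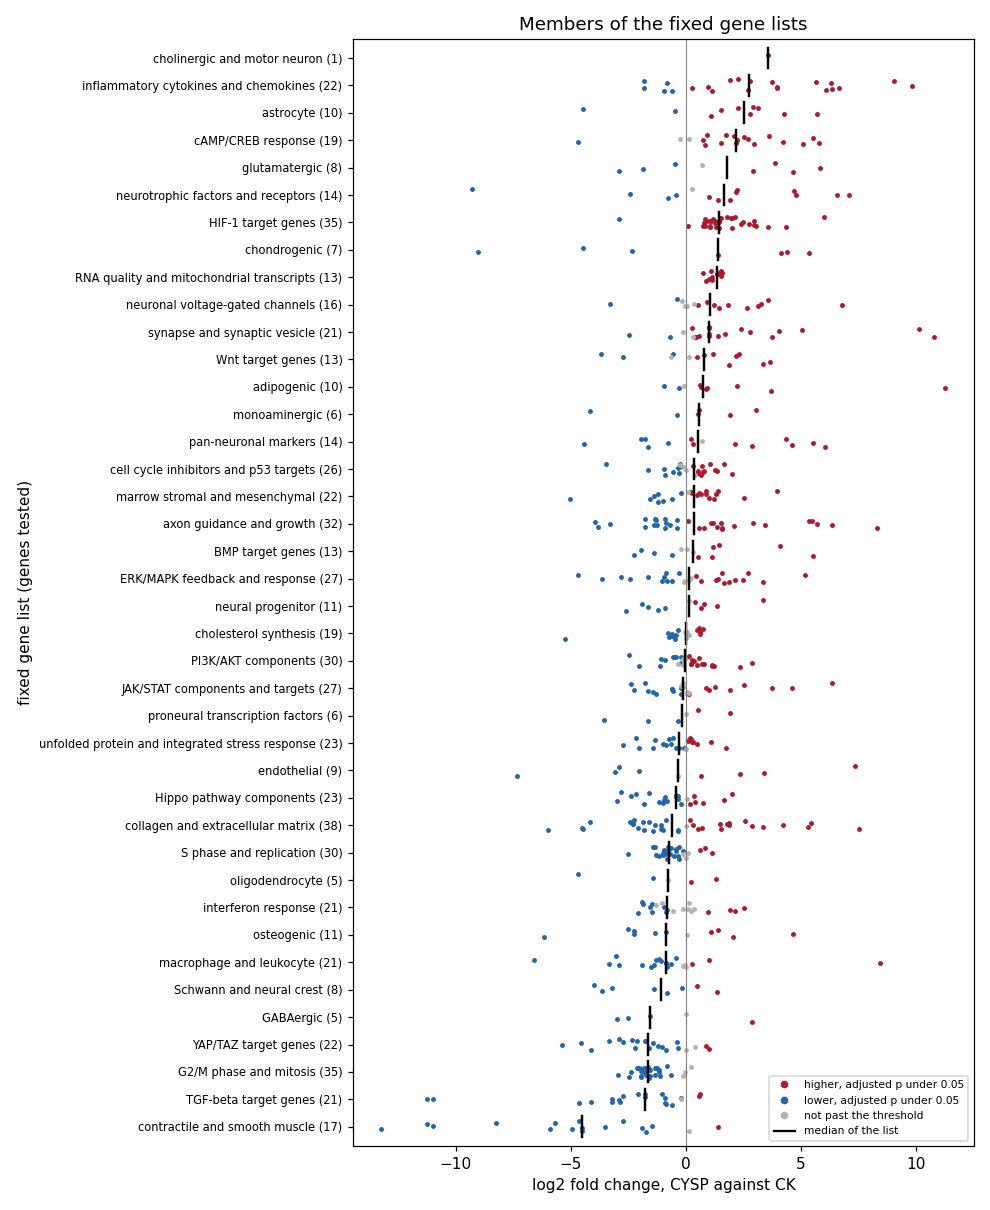
Log2 fold change of CYSP against CK for each tested member of the 40 fixed gene lists, with 1 point per gene, a bar at the median of each list and the number of genes tested in parentheses. The contractile list has a median of -4.52 and the HIF-1 list of 1.44. Points for genes with 0 counts in a group (Sv2b, Ntrk3 and Acta1 among them) are fitted values that depend on the prior count.

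Over the 40 lists, 7 were higher and 7 lower by camera with a preset correlation of 0.01. With an estimated correlation 0 of the 40 passed, 7 had an unadjusted p under 0.05, and the smallest adjusted p was 0.13. By fry, which asks whether the genes of a list move one way and not whether they stand apart from other genes, 19 were higher and 15 lower. List medians were the same with genes at 0 in a group set to their bound, a change that could hardly move them. The bounds of Sv2b, Ntrk3 and Acta1, for example, lie on the same side of their list medians as the fitted values.

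The authors' deposited table calls 1947 genes higher and 1919 lower at an adjusted p under 0.05 and an absolute log2 fold change over 1. Of those 3866 genes in the authors' deposited table, 3482 passed the count filter here, and all 3482 were past the threshold in the same direction, 3312 of them also with the fold. Another 203 genes were past the threshold and the fold here and not in the authors' deposited table. The fold changes of the authors' deposited table, made from mean FPKM, and those fitted here had a Pearson r of 0.999 across the 12539 tested genes with both group means above the floor of the authors' table, which are not independent replicates and come from the same samples. The fold changes of the authors' deposited table lay a median of -0.083 from those fitted here, on the log2 scale. Library size as the only scaling also moved the fitted fold changes by a median of -0.083.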

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

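The fits with an assumed biological coefficient of variation (BCV) and without mitochondrial transcripts were chosen after the data were seen. All 9600 genes past the threshold kept their direction wherever they passed it again, and between 8484 and 9600 passed under the other scalings, tools, filters, block and left-out samples. Exceptions are glmTreat, which tests against a fold and passed 2721 of them, and an assumed BCV of 0.2 or 0.4, with 5883 and 2698. Leaving out each sample in turn gave 4706 to 4751 genes higher and 4621 to 4687 lower, and with the fold 1940 to 2022 higher and 1616 to 1660 lower. An assumed BCV of 0.2 gave 3102 higher and 2801 lower and 0.4 gave 1496 and 1209, since more spread was assumed. The balance of directions turned with scaling: upper quartile scaling gave 4722 higher and 4891 lower, and library size alone 4345 and 5290. Limma-trend on log2(FPKM + 1), which also changes the test, the measure and the genes tested (11994), gave 3968 and 5049. With the fold library size alone gave 1775 higher and 1753 lower. Limma-trend gave 1105 higher and 1136 lower with the fold, on a scale that understates low genes. A threshold of 2 on the log2 scale gave 885 higher and 620 lower, by construction. Without mitochondrial transcripts 4867 genes were higher and 4736 lower, 1936 and 1585 with the fold, and 9549 of the 9587 calls still tested were kept. The replicate numbers did not pair the samples: deviations of same-numbered samples correlated between -0.00885 and 0.0185. The fit with the replicate block gave 4773 higher and 4712 lower, and 1923 and 1592 with the fold.

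With an estimated correlation camera called 0 lists, 0 KEGG terms and 0 GO processes in either direction, with 7, 40 and 70 at an unadjusted p under 0.05. Fry gave 19 lists higher and 15 lower, 169 and 102 KEGG terms, and 604 and 608 GO processes, since it does not compare a set with other genes. Against camera, fry turned the direction of the glutamatergic (median 1.81), proneural (-0.17), neural progenitor (0.14), chondrogenic (1.38) and JAK/STAT (-0.12) lists, none of which passed camera. For the term counts that follow, the cause was not tested. DESeq2 gave 17 KEGG terms lower, and 57 GO processes higher and 36 lower. Limma-voom gave 14 KEGG terms lower, and 28 GO processes higher and 20 lower. With no filter 17 KEGG terms were higher and 24 GO processes lower, and with the stricter filter 3 KEGG terms were lower. Limma-trend gave 17 GO processes higher. KEGG terms lower ranged from 3 (without CK replicate 3) to 7 with a sample left out. The synapse, channel and S phase lists lost their call with DESeq2 (adjusted p = 0.12, 0.25 and 0.1), and the channel list also with limma-voom, limma-trend and the stricter filter. The adipogenic list gained one with DESeq2, limma-voom and limma-trend (0.022, 0.049 and 0.034), and the pan-neuronal list with DESeq2 (0.044). Fold changes of genes taken by the naming rule kept direction and call in 4096 cases and lost the call in 113, with 0 reversed. The pseudocount of 0.1 and the unfiltered FPKM fit, planned for a table without counts, were not run. Genes with few counts, Rbfox3, Nefl, Nefm, Syp and Gfap among them, are limited by depth.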

Other observations

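The genes named in the first 2 paragraphs, the terms picked out for them and most tests of explanations were chosen after their values were seen; the tests of other splits and of transcript length were set before. Among annotation terms, camera with the preset correlation called 26 KEGG terms higher and 5 lower, and 8 GO processes higher and 12 lower, and with an estimated correlation the smallest adjusted p was 0.33 for KEGG and 0.74 for GO. Ribosome (127 of 185 genes higher), Lysosome (82 of 118) and Glycolysis / Gluconeogenesis (38 of 49) were higher, with adjusted p of 2.9e-06, 2.1e-04 and 2.1e-04. Spliceosome (87 of 129 genes lower) and Cell cycle (78 of 121) were lower, with adjusted p of 2.1e-04 and 9.5e-04. Aldh3a1, an aldehyde dehydrogenase, rose from 0.319 ± 0.195 to 310 ± 9.23 CPM (n = 3 per group), and Mgst1 and Gsta4, glutathione transferases, rose by log2 fold changes of 4.12 and 4.09. The iron storage gene Fth1 rose from 776 ± 11.4 to 5970 ± 65.4 CPM, and the siderophore-binding gene Lcn2 from 3.22 ± 1.04 to 1510 ± 5.41 CPM.

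Of 909 tested genes with a transcription factor family in the deposited annotation, 258 were higher and 410 lower. Over all 12623 tested genes the counts were 4828 higher and 4772 lower. No set test was run on the transcription factor genes, and their counts were not repeated with other scalings. Hif1a and Epas1, which encode oxygen-regulated subunits of the hypoxia-inducible factors, rose from 275 ± 17.6 to 1510 ± 40.3 CPM and from 34.5 ± 5.83 to 249 ± 5.66 CPM. Vdr, the vitamin D receptor, and Osr1 fell, with log2 fold changes of -3.92 and -3.89. The GO process actin cytoskeleton organization had 93 of 146 genes lower and 35 higher, with a median log2 fold change of -0.42 (camera adjusted p = 0.004, and adjusted p = 0.74 with an estimated correlation). Flna, an actin cross-linker, and Vcl, a protein of focal adhesions, had log2 fold changes of -2.98 and -3.65. Actb and Actg1 encode the cytoplasmic actins, and both were lower in CYSP (log2 fold changes -2.34 and -1.19).

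The count of genes past the threshold was compared with the other splits of the 6 samples into 3 and 3. Of the 10 splits 1, the real one, gave as many as its 9600 genes, and the highest of the others gave 0. With the fold the real split gave 3515 genes, again matched by 1 of 10 splits, and the highest other 0. In the other splits edgeR called 18 to 27 genes at an unadjusted p under 0.05, DESeq2 at most 1 adjusted and limma-voom 0. Every other split mixes CK and CYSP samples, so the difference between groups enters its spread. Few or no calls were therefore bound to follow, and the comparison says nothing on chance. With 10 splits the share cannot go under 0.1.

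The spread between samples of a group was very small. Repeat sequencing of 1 library would leave sampling noise alone, with a mean chi-square per gene near 1 if each count is an independent read. The lowest of the 6 pairs within a group had 2.1. How reads were counted is not given, and reads counted more than once would raise this value too, so the test cannot decide. Repeat libraries from 1 culture also stay open. The coefficient of variation of 0.039 lies between the bounds set for that test, and cultures handled alike could give it too. The labels settle neither question.

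Mitochondrially encoded transcripts were higher in CYSP. The median log2 fold change was 1.35 with TMM and 1.26 with library size as the only scaling. With TMM factors of 0.967 to 1.03 it could hardly have moved further. Both scalings are relative to the counts of each library, so this comparison says nothing about amounts per cell. Abundant nuclear transcripts in the same length range, as counts and FPKM imply it, had a median of 0.32 over 350 genes. The median over all tested genes was 0.00461. This argues against transcript length, or RNA integrity acting on length, as the whole of the rise, while a smaller part linked to length stays open. An equal rise of the whole respiratory chain is argued against by the nuclear-encoded oxidative phosphorylation genes, with a median of 0.34 over 104 genes and an upper quartile of 0.627, under the lower quartile of 1.09 of the mitochondrial transcripts. More mitochondrial transcription per cell, slower decay, and loss of cytoplasmic RNA from damaged cells were not tested and stay open.

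Of 22 tested cytokine genes 17 were higher in CYSP, and of 21 macrophage and leukocyte genes 15 were lower. Both list calls were lost with an estimated correlation (adjusted p = 0.56 and 0.39). The median log2 fold change of -0.87 over the leukocyte list argues against a higher share of macrophages only if expression per macrophage stayed the same. That condition was not tested, and the members moved unequally. The abundant member Lyz2 fell from 883 ± 54.2 to 108 ± 4.07 CPM, while Cd163 and Mrc1 rose. Cd14, C1qb and C1qc did not pass the threshold, with log2 fold changes of 0, -0.12 and -0.04. Activation of the macrophages present cannot be told apart from expression by the stromal cells: the median of the cytokine list lay 3.62 above that of the leukocyte list, which either could give in RNA from mixed cells.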
